A study of Mus musculus with 4 samples.

How the data were processed

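Total RNA was extracted from sorted mouse bone marrow cells, amplified, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols and the series' design text. That text names a human array, but the probe sets of the value table carry the names and annotation of a mouse array, and they were used as such. There were 2 arrays per area, and the group and replicate number of each array came from its title.

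The deposited values are log2 expression. RMA (background correction, quantile normalization and median polish) is named in the submitters' processing notes, with no version. The deposited values were also centred per probe set: for all 45101 probe sets of the deposited table the median over the 4 arrays is 0, to within the rounding of the numbers. The software used for the centring, any filter and the log base are not given in the sources used here. The median of each array's values was 0.01, -0.01, -0.01 and 0.02 for trabecular arrays 1 and 2 and long bone arrays 1 and 2. Log base 2 is what RMA gives, and the number steps bear on it. Numbers stored with 32 bits have a step of a fixed power of 2 that depends on their size before centring, and of 41693 probe sets whose step could be read 33.7% had the step of levels of 8 and above, 62.4% that of levels of 4 to 8 and 3.88% that of levels of 2 to 4. These are the levels that RMA values on the log2 scale take. On simulated values the reading called 100% of probe sets at 8 to 16 bright, 6.28% at 4 to 8 and 0.593% at 2 to 4. Each simulated probe set stayed within 1 band, so the error for probe sets that cross 8 was not measured. A probe set was read only with at least 3 values of 0.001 or more in size, which left out 719, and where 1 step fitted all its values, which left out a further 2689. Each of these 2689 had a value of 0.0156 or less in size.

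Centring leaves differences between arrays as they were and removes all levels. Folds between areas are therefore valid on the RMA scale, on which folds of dim genes are compressed, while levels of different genes cannot be compared beyond the coarse bands that the number steps give, which also depend on the probes' affinity. Some choices made before the data were examined could not be kept for this reason. A gene was to be represented by its brightest probe set, and was instead given the mean of all probe sets annotated to it alone, which had been foreseen as another way to do it. The filter on dim probe sets and the level condition in the rule for named genes were dropped.

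Of the 45101 probe sets, 64 controls were left out of the tests. Of the remaining 45037, 34945 had 1 gene, 932 several and 9160 none in the annotation used here, and only the first were named. They gave 18193 genes, 9010 of them with more than 1 probe set. Symbols were checked by gene ID against RefSeq genes of GRCm38.p6 (34741 probe sets matched, 0 symbols changed), and no coordinates were used.

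The areas were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, 2 residual degrees of freedom, prior degrees of freedom 2.17), trabecular minus long bone area, without the replicate number as a block. P-values were adjusted with Benjamini-Hochberg, called at 0.05. Probe sets at least 2-fold apart with no overlap were counted for the areas and for the 2 other pairings of the arrays. Gene lists of pathways, of bone and marrow cell types, and of other cells that the sort could hold were fixed beforehand too, 842 genes in all, of which 78 were not analysed here. The 39 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each two-sided. With an estimated correlation camera uses the 2 residual degrees of freedom, so hardly any list could pass whatever its shift. Named genes are the sorting antigens, Notch and niche genes chosen beforehand (3 of these not analysed here), up to 2 members per list and direction, and the 12 largest differences per direction. As no gene was called, these 12 were filled by size among genes with no overlap between areas, passing over 1 predicted gene. Further list members named in the text, and the genes named for 1 array, were picked after their values were seen. Intervals of single differences are 95% intervals from the moderated fit, and those of list medians come from 10000 bootstrap draws of genes.

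The test was tried on simulated values with the spread of these arrays. Of simulated 2-fold changes 0 of 67 were called at the adjusted threshold (63 at an unadjusted p under 0.05), of 4-fold changes 16 of 67, and of 16-fold changes 50 of 66, with 1 unchanged probe set called. In simulated lists with no shift 0 of 39 were called, and a list of 13 genes shifted by 1 on the log2 scale was called. The simulated genes were independent of each other, as the genes of a list in a real sample are not. Arrays were compared before averaging. Between any pair 65 to 107 probe sets held identical values, and the SD of the log2 difference was 0.357 for the trabecular pair, 0.532 for the long bone pair and 0.482 to 0.674 between areas, so no array was a copy of another.

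The alternatives were the replicate block, each array left out, quantile normalization or median centring of the deposited values, a trend or robust prior, an added fold threshold, ordinary t statistics, other fold thresholds and the list tests named above. Added after seeing the data were the restriction to bright probe sets, the crossed pairing, and the counts of genes and of probe sets at an unadjusted p. Values were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.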

Results

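Gene expression was measured in bone-forming cells sorted from the bone marrow of immunodeficient NOD/SCID mice, a strain whose scid mutation blocks the development of mature B and T cells. The sort kept cells that carried the integrin CD51 and lacked CD45 (blood cells), CD31 (endothelium), Sca1 and the lineage antigens of mature blood cells. The cells came either from the trabecular bone area, the spongy part of the bone, or from the long bone area. Each area was measured on 2 arrays, which the submitters call biological replicates. The labels do not say which mice the replicates came from, so the p-values below measure only the spread between these samples. The series title puts the work in a study of where human blood stem cells lie in the marrow and how that place bears on them. The comparison between the areas asks how cells of the bone-forming sort differ between these 2 places.

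The deposited values are log2 expression relative to the median of the 4 arrays, so each gene carries a difference and no level. No gene is given as on or off for this reason. The log2 SD over 45037 probe sets was 0.312 and 0.271 on trabecular arrays 1 and 2, and 0.305 and 0.484 on long bone arrays 1 and 2. Long bone array 2 stood apart. On it 2493 probe sets lay at least 2-fold from the 4-array median, against 383 to 848 on the other arrays. The 5' minus 3' difference of the Gapdh control, a sign of RNA integrity and of the reach of the amplification, was -1.16 on long bone array 2 and between -0.09 and 0.31 on the others. The same difference of the Actb control did not single this array out, at -0.04 against 0.44 and -0.07 in the trabecular area and 0.07 on long bone array 1. The 9 hybridisation control probe sets read transcripts spiked into every sample, with more than 1 probe set per transcript. All 9 were lower on both trabecular arrays than on both long bone arrays, with a median log2 difference of -0.39. The 12 labelling control probe sets, for transcripts added before labelling, had medians of -0.30 and 0.28 on trabecular arrays 1 and 2. Their medians were 0.42 on long bone array 1 and -0.75 on long bone array 2, with a median difference between the areas of 0.13. On long bone array 2 their middle probe sets lay below the 3' ones, at -2.15 against -0.75 for DapX and -1.84 against -0.61 for ThrX. The 5' probe sets went both ways there, at -0.74 against -0.06 at the 3' end for PheX and -0.28 against -0.61 for ThrX. The number of arrays, 2 per area, limits the precision of every value.

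Cartilage genes stood out among the largest differences between the areas, lower in the trabecular samples: of the 12 genes with the largest differences in that direction, 6 were on the chondrocyte list. Comp, a cartilage matrix protein that binds collagen, was 36.2-fold lower, with a mean log2 value of -2.58 ± 0.54 in the trabecular area and 2.60 ± 0.57 in the long bone area (SD, n = 2 each). Col2a1, the main collagen of cartilage, was 13.6-fold lower (log2 difference -3.77, SE 0.29). Matn3 and Col9a1, a cartilage adaptor protein and a fibril-associated cartilage collagen, were 11.6-fold and 8.25-fold lower. The log2 difference was -4.07 for Col11a1, -3.96 for the small proteoglycan Fmod, -3.95 for the collagenase Mmp13, -3.87 for the matricellular protein Ccn2, -3.41 for the scavenger receptor Scara3 and -3.32 for Chad. Prg4, the lubricant of joint surfaces, and Wif1, a secreted Wnt inhibitor, had differences of -4.41 and -3.79. Both stood far higher on long bone array 1 than on any other, Prg4 by 5.74 and Wif1 by 3.49, and without it the differences were -1.54 and -2.05.

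The genes with the largest differences in the other direction, higher in the trabecular area, differed by less. The largest log2 difference was 2.25 for Rhov, a small GTPase, followed by 2.06 for the chemokine Ccl6 and 2.04 for Dusp6, a phosphatase that acts on ERK. Dusp6 was tight within each area (1.13 ± 0.43 against -0.92 ± 0.13, SD, n = 2 each), as was Pmaip1, a pro-apoptotic BCL2 family gene (difference 1.77, SE 0.18). The activation antigen Cd69 (1.92), the zinc finger gene Zfp119b (1.85), the eosinophil ribonuclease Ear3 (1.84), Tmem154 (1.82), Osgin1 (1.80), the cannabinoid receptor Cnr2 (1.80), the myeloid receptor Trem1 (1.72) and the cysteine protease inhibitor Stfa3 (1.69) completed the 12 largest. Most of these values depended on single arrays. Cd69 was at 0.19 without long bone array 1. The difference was 0.73 for Ear3, 0.98 for Tmem154 and 1.04 for Cnr2 without long bone array 2. Without trabecular array 1 it was 1.10 for Ccl6, 1.16 for Zfp119b, 1.02 for Trem1 and 1.05 for Stfa3. Osgin1 was at 1.20 without long bone array 1.

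None of these 24 genes passed the test. With limma, 0 of 45037 probe sets and 0 of 18193 genes had an adjusted p under 0.05 (1 probe set with ordinary t statistics, and 281 with a trend in the prior variance, 36 higher and 245 lower), and the lowest adjusted p was 0.0609 for probe sets and 0.0991 for genes. The number of probe sets at an unadjusted p under 0.05 was 7325 (16.3%, where chance gives 5%), 4017 of them higher and 3308 lower in the trabecular area, and that of genes 2811, 1971 higher and 840 lower. The count of probe sets depended on single arrays. It was 2673 without trabecular array 1, 3319 without trabecular array 2, 12789 without long bone array 1 and 6572 without long bone array 2. In the fit without long bone array 1, which takes its spread from the trabecular pair alone, 1603 genes passed the adjusted threshold, 1053 higher and 550 lower, among them 15 of the 24 named genes. In the fit without long bone array 2, 1 gene passed, Prg4.

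There were 2179 probe sets at least 2-fold apart with no overlap between areas, 959 higher and 1220 lower in the trabecular area. Per gene the balance was the other way, with 266 genes higher and 213 lower. At 4-fold there were 16 probe sets higher and 274 lower. The other ways to split the 4 arrays into pairs gave 236 probe sets for the split by replicate number and 735 for the crossed split. No overlap by itself held for 52.1% of probe sets, where chance gives 33.3%. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333 (two-sided). Without long bone array 1 the 2-fold count was 4746.

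**Figure D1:**
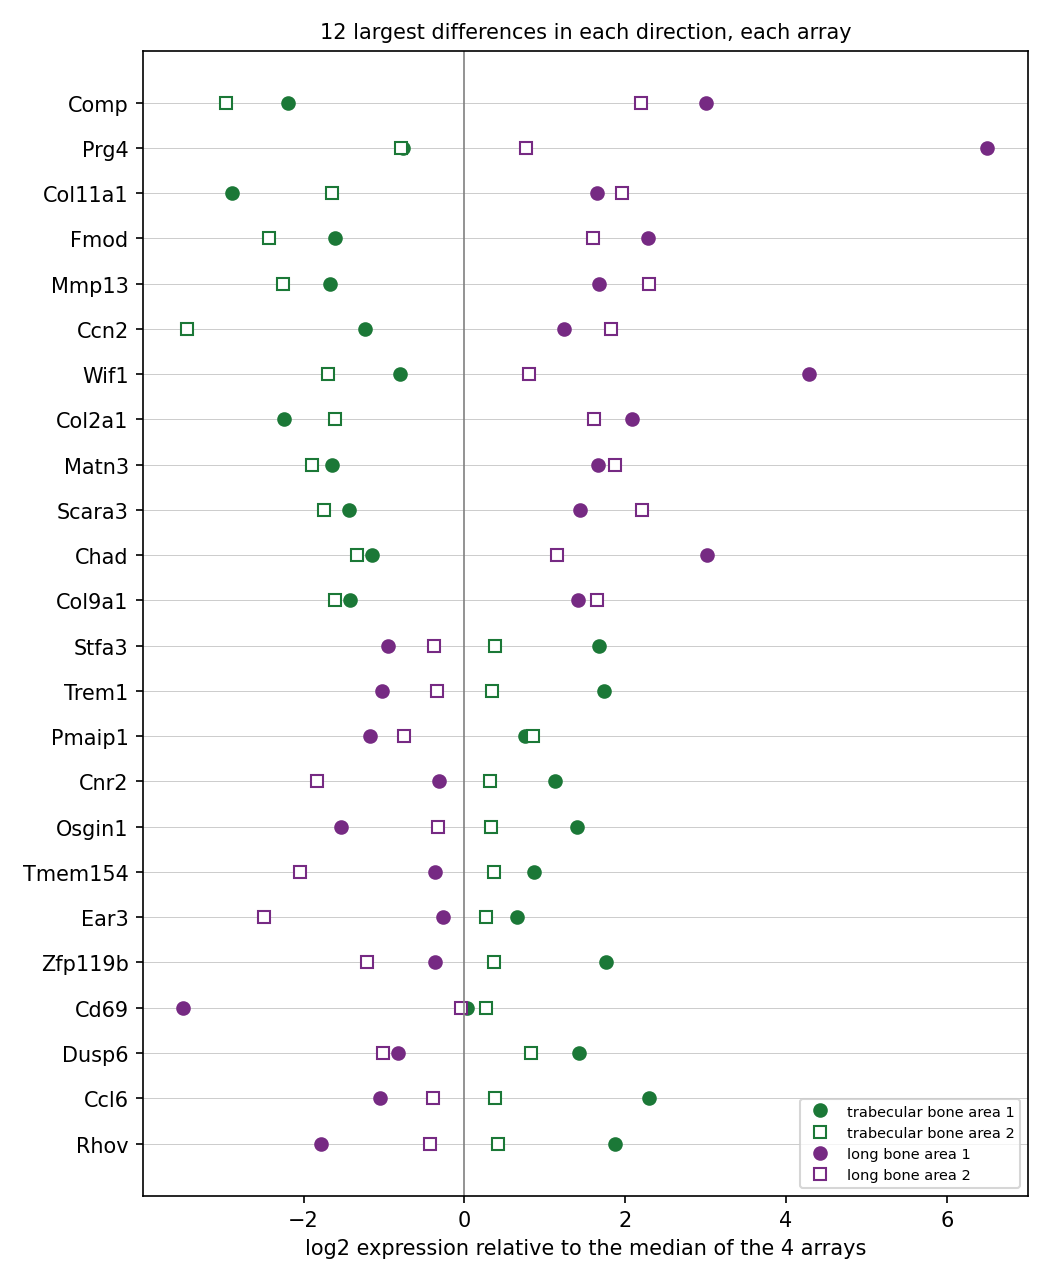
Each line is 1 of the 24 genes with the 12 largest differences in each direction, and each point is the log2 expression of 1 array relative to the median of the 4 arrays, green for the trabecular and purple for the long bone area. The cartilage gene Comp lies at -2.20 and -2.96 in the trabecular area and far above 0 on both long bone arrays (mean 2.60), while Prg4 lies 5.74 higher on long bone array 1 than on any other array.

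Of 21 measured chondrocyte genes, all 21 were lower in the trabecular area, 19 with no overlap, and the median log2 difference was -1.79. Besides the genes above, Hapln1, which links proteoglycans to hyaluronan, differed by -3.03, Cnmd by -2.77, Col9a3 by -2.38 and Acan, the main proteoglycan of cartilage, by -1.75. The transcription factors of the lineage differed less, Sox9 by -0.24, Sox5 by -0.16 and Sox6 by -0.46, and Col10a1, the collagen of hypertrophic cartilage, by -0.27 (0.04 without long bone array 2). Acan was at -1.02 and Sox9 at -0.11 without long bone array 1. Adjusted over the list alone, 16 of the 21 were called, and 0 over all genes. In camera with a preset correlation of 0.01 the list was lower at an adjusted p of 3.43e-19, over 39 lists, and the adjusted p was 0.291 with an estimated correlation. The estimate was 0.00395, below the preset value, so a higher correlation does not account for the weaker adjusted p. That form of the test rests on 2 residual degrees of freedom and has little power. The median was -1.10 without long bone array 1 and -2.45 without long bone array 2.

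Fibrillar matrix genes were lower in the trabecular area in 30 of 32 cases, 26 with no overlap, with a median of -1.30. Bgn and Dcn, proteoglycans that bind collagen fibrils, differed by -2.60 and -2.19, Col6a1 by -2.49, the adhesive glycoprotein Tnc by -2.43 and Serpinh1, a collagen chaperone, by -1.37. Plod1, a collagen-modifying enzyme, and Thbs1 differed the other way, by 0.25 and 0.69 (0.15 and 0.28 without trabecular array 1). Adjusted over the list alone, 19 were called, and 0 over all genes. The adjusted p was 2.52e-18 with the preset and 0.291 with an estimated correlation.

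Osteoblast genes, the type the sort aimed at, were lower in 17 of 18 cases, with a median of -0.42. The members with the largest differences were matrix genes. Col1a2 differed by -2.46, Sparc by -2.35 and Omd (osteomodulin) by -1.57, and Ibsp (bone sialoprotein) was 3.99-fold lower. These 4 were the ones called over the list alone, and 0 were called over all genes. Col1a2 and Sparc are also on the fibrillar matrix list. Alpl, the alkaline phosphatase of mineralising cells, differed by -0.66 (-0.30 without long bone array 2), and Sp7, a transcription factor needed for osteoblasts, by -0.38. Atf4 was the exception at 0.36 (0.18 without trabecular array 1). The list was called at an adjusted p of 3.07e-07, and the adjusted p was 0.635 with an estimated correlation. Osteocyte genes had a median of -0.35 (14 of 15 lower, 2 called over the list alone and 0 over all genes), with Ackr3 at -2.75 and the osteocyte matrix gene Dmp1 at -0.96 (-0.51 without long bone array 1), while Sost, the sclerostin gene, was at -0.01, with a sign that turned after quantile normalization and with 1 array left out. That list was called at an adjusted p of 0.000852 and lost the call with an estimated correlation (adjusted p = 0.635). Without long bone array 2 the medians were -0.27 for osteoblast and -0.12 for osteocyte genes, and without long bone array 1 the osteoblast median was -0.63.

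Genes of blood stem cell support were lower in 25 of 28 cases, with a median of -0.50. Il6 differed by -2.65, and it was called over the list alone with Tnc, Fn1 and Postn, while 0 members were called over all genes. Tnc, Fn1 and Postn are also on the fibrillar matrix list, so these calls are not independent of it. Cxcl12, which retains stem cells in the marrow, and Kitl, the ligand of the Kit receptor, differed by -1.43 (95% interval -3.75 to 0.88) and -0.86 (-2.27 to 0.55), and both overlapped between the areas. Angpt1 differed by -0.53 and Vcam1 by -0.26. These 4 values depended on long bone array 2. Without it Cxcl12 was at -0.39, Kitl at -0.17 and Angpt1 at -0.17, and Vcam1 turned to 0.29. The list's adjusted p was 1.72e-06 with the preset and 0.635 with an estimated correlation, and its median was -0.17 without long bone array 2 and -0.89 without long bone array 1.

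Reticular stroma genes, which mark the Cxcl12-rich cells of the marrow, followed 1 array. Their median value was 1.41 on long bone array 2, and 0.05, -0.49 and -0.08 on trabecular arrays 1 and 2 and long bone array 1. The median difference of -0.96 (16 of 18 lower, 0 called over the list alone or over all genes) was -0.13 without that array, and the list was then no longer called (adjusted p = 0.159 against 0.00126 with all arrays, over alternatives from 1.75e-07 to 0.689). The median log2 difference of the list reticular stroma was -1.75 without long bone array 1. With an estimated correlation the adjusted p was 0.669. Lepr, the leptin receptor that marks these cells, was 1.63 above the 4-array median on that array, Ebf3 1.76, Cxcl12 1.89 and Esm1 4.71. Of the genes of the fat lineage, Adipoq was 4.49 above the median on the same array and Pparg 1.30, but the adipocyte list was not called (median -0.09, adjusted p = 0.518).

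The Notch pathway list was not called. Of 30 measured members 13 were higher and 17 lower in the trabecular area, with a median of -0.04 (adjusted p = 0.409). The ligand Jag1 differed by 0.25 (95% interval -0.11 to 0.62), Jag2 by -0.02, Dll1 by -0.45 and Dll4 by -0.15. The receptor Notch1 differed by 0.58 and Notch2 by -0.19, and the target genes Hes1 and Hey1 differed by -0.53 and -0.04. Notch1 was at 0.18, Hes1 at -0.01 and Dll4 at -0.07 without long bone array 2, and Jag2 and Hey1 turned to 0.12 and 0.06. The sign of Jag2 also turned after quantile normalization (0.03). Jag1 was at 0.16 without trabecular array 1. No Notch gene was called, over all genes or over the list alone.

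Energy metabolism genes were higher in the trabecular area. Of 29 oxidative phosphorylation genes 28 were higher, with a median of 0.33, led by the complex III subunits Uqcrfs1 (0.83) and Uqcrc1 (0.76). Of 22 genes of glycolysis and hypoxia 18 were higher, with a median of 0.53, among them Pgam1 (0.93), the glucose transporter Slc2a3 (0.76), Tpi1 (0.69) and Ldha (0.62). Interferon response genes were higher in 18 of 24 cases, with a median of 0.35, led by Oasl2 (1.44), Ifit2 (0.92) and Ifit1 (0.92), genes induced by interferon, while Mx1 differed by -0.38 and Rsad2 by -0.44. No member of the 3 lists was called, over all genes or over the list alone. The adjusted p was 3.96e-05, 0.000852 and 0.0154 with the preset correlation, and 0.635 for each with an estimated correlation. The oxidative phosphorylation median was 0.21 without trabecular array 2. Without long bone array 2 the glycolysis median was 0.28, with Pgam1 at 0.59 and Ldha at 0.32, and Rsad2 was at -0.06. Ifit2, which overlapped between the areas, was at 0.08 without long bone array 2. Slc2a3 was at 0.49 and Ifit1 at 0.58 without trabecular array 1. The spiked hybridisation controls differed by -0.39. Of 9 reference genes 8 were higher in the trabecular area too, among them Hprt at 0.36, B2m at 0.45, Pgk1 at 0.55 and Ywhaz at 0.70, while Actb, over 2 probe sets, was at -0.95. The control probe sets for Actb did not share that drop. The 3' control was at 0.16 and -0.05 on trabecular arrays 1 and 2, and at 0.05 and -0.53 on long bone arrays 1 and 2. Of these reference genes, Pgk1 and Sdha are also on the glycolysis and oxidative phosphorylation lists. Hprt was at 0.15 without long bone array 2.

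The other 11 called lists were lower in the trabecular area. The median was -0.57 for tendon, periosteum and fibroblast genes (14 of 17 lower, 4 called over the list alone), -0.42 for smooth muscle and pericyte genes (15 of 17 lower), -0.40 for the insulin-like growth factor pathway (13 of 15 lower, 1 called over the list alone), -0.38 for basement membrane (16 of 17 lower) and -0.35 for angiogenic factors (15 of 19 lower). The tendon list shares Dcn, Lum and Aspn with the fibrillar matrix list. Matrix remodelling went both ways, with a median of -0.31, 19 of 26 lower and 2 called over the list alone, Mmp13 and Ctsk. Of its members higher in the trabecular area, Mmp9 differed by 1.52, Mmp8 by 1.12 and Plaur by 1.08, and over bright probe sets alone the median was 0.36. Mmp9 was at 0.91 without long bone array 2, and Mmp8 at 0.73 without trabecular array 1. The median was -0.26 for the hedgehog pathway, -0.24 for dendritic cell genes, -0.18 for the Wnt pathway, -0.17 for the BMP and TGF-beta pathway and -0.17 for B cell and plasma cell genes. In the BMP list, Bmp2 differed by -1.78 and the receptor Bmpr1a by 0.54, and in the insulin-like list the protease Htra1 differed by -2.72. Over all genes 0 members were called. The hybridisation controls differed by -0.39. With an estimated correlation none of these lists held, at adjusted p between 0.635 and 0.692. Without long bone array 2 the 11 medians lay between -0.21 and 0.02, and without long bone array 1 between -0.69 and -0.21. Without long bone array 2 the calls of smooth muscle (median -0.14), BMP (-0.01) and B cell genes (0.02) ended, as did that of BMP genes without trabecular array 2 (-0.14). Across all 39 lists camera called 20 with the preset correlation, 17 lower and 3 higher. It called 0 with an estimated correlation. A higher correlation does not account for every lost call. The estimates for the chondrocyte and interferon lists, 0.00395 and 0.00068, lay below the preset 0.01. The form with an estimate takes its p-values from 2 residual degrees of freedom. Hardly any list could pass it here, so a lost call does not count against a list. Fry, which asks whether a list's genes move 1 way on balance, called 0 (6 at an unadjusted p under 0.05, lowest adjusted p 0.0543). The crossed split of the arrays called 19 lists with the preset correlation and the split by replicate number called 6, so the number of preset calls does not single out the split by area. The chondrocyte list, which had the largest median difference by area, had a median of -1.79 in that split. It was -0.11 in the crossed split and 0.02 in the split by replicate number.

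**Figure D2:**
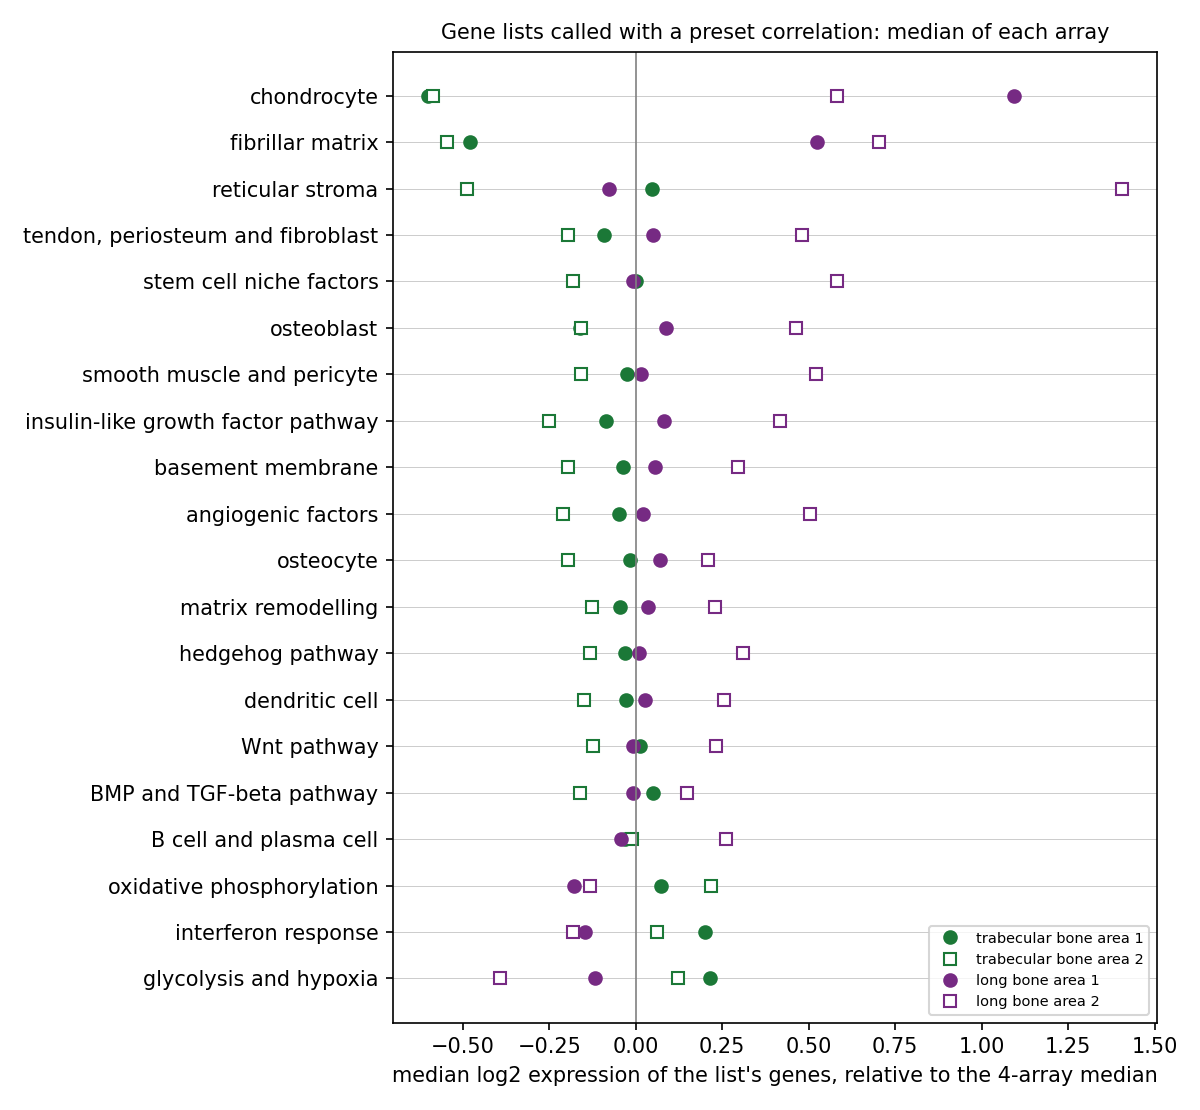
Each line is 1 of the 20 gene lists called with the preset correlation, and each point is the median log2 value of the list's genes on 1 array, relative to the 4-array median, green for the trabecular and purple for the long bone area. The chondrocyte and fibrillar matrix lists part the areas, whereas the reticular stroma list lies at 1.41 on long bone array 2 and near or below 0 on the other arrays.

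Among the genes of the sorting antigens, Ptprc, which encodes CD45, differed by -0.34 (95% interval -1.41 to 0.73, and 0.20 without long bone array 1), Pecam1, which encodes CD31, by -0.02 (0.05 without trabecular array 2), and Itgav, which encodes CD51, by -0.13. The lineage antigen gene Itgam, a myeloid integrin, differed by 1.68 (0.85 without long bone array 2), and Cd3d, a T cell receptor component, by 1.66, both with no overlap between areas and neither past the test. Other T cell genes did not share the size of the Cd3d difference. Cd3g differed by 0.28 (0.04 without trabecular array 1), Cd8a by -0.01 and Cd4 by -0.23. Of 20 measured T and NK cell genes 6 were higher and 14 lower in the trabecular area. None of the lists of other blood cells was called apart from the dendritic and B cell lists. The median was 0.09 for neutrophil lineage, -0.09 for monocyte and macrophage, -0.10 for erythroid and -0.12 for megakaryocyte and platelet genes. It was -0.05 for mast cell, basophil and eosinophil, -0.13 for stem and progenitor cell, 0.08 for osteoclast and -0.10 for T and NK cell genes. Of the osteoclast list 1 gene was called over the list alone, Ctsk, which was lower in the trabecular area at -0.73. The endothelial median was -0.05, the Schwann and nerve median 0.05 and the skeletal muscle median 0.02. Of the remaining lists, ribosomal proteins had a median of 0.16, cell cycle 0.14, immediate early and heat shock genes 0.11, cell adhesion -0.16, cytokines and chemokines -0.14 and osteoclast regulation by stroma -0.22, none called. With 1 array left out the median turned in 13 of the 19 lists that were not called. Without trabecular array 2 it was -0.03 for ribosomal proteins and -0.03 for cell cycle genes, and without long bone array 1 it was -0.17 for immediate early genes. Medians that kept their sign moved as well. Without long bone array 2 they were -0.05 for cell adhesion, -0.005 for cytokines and chemokines and -0.07 for osteoclast regulation by stroma. The median, mean and test differed in sign for 5 lists that were not called, T and NK cell, skeletal muscle, Notch, Schwann and nerve, and immediate early genes.

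Neutrophil lineage transcripts were read as bright on every array, although CD45 and lineage antigens had been gated out. The fine step of the stored numbers, taken as 32-bit numbers before centring, was used to read whether a probe set lay at a log2 level of 8 or above on all 4 arrays. All 15 neutrophil lineage genes whose step could be read were read so, among them the granule genes Ltf, Ngp, Lcn2, Mpo and Elane and the lysozyme gene Lyz2. A gene counted where at least 1 of its probe sets was read so, and other probe sets of Itgb2l were not. S100a8, S100a9 and Camp could not be read. Over all genes the share was 48.2% (8405 of 17439), in the osteoblast list 33.3% (6 of 18), in the chondrocyte list 30% (6 of 20) and in the T and NK cell list 25% (5 of 20). Other lists were high as well. The share was 100% in the oxidative phosphorylation list, 96.8% in cell cycle, 92.3% in immediate early and heat shock, 90.9% in ribosomal protein and 86.4% in glycolysis genes, and the reference genes were bright in 8 of 8 cases. Of other blood cell lists it was 60% in erythroid (9 of 15) and 57.1% in monocyte and macrophage genes (12 of 21). Brightness depends on the probes as well as on the amount of RNA. The reading counts genes that stayed bright on all arrays, so a gene that was much lower in 1 area is missed by it.

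**Figure D3:**
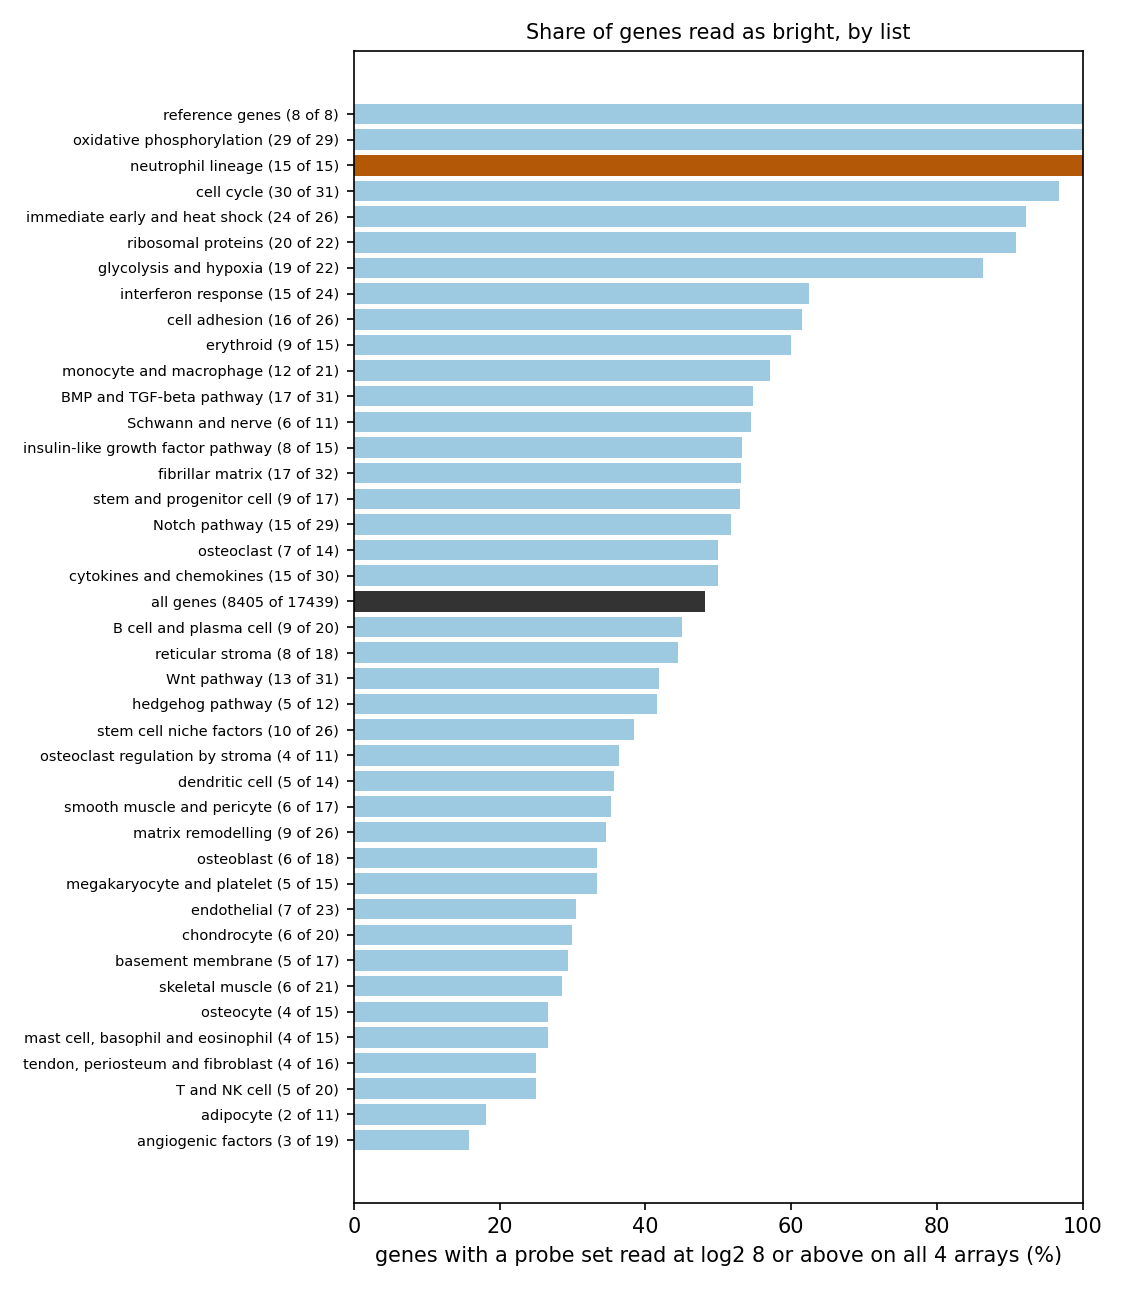
Bars give the percentage of genes in each list with at least 1 probe set read at a log2 level of 8 or above on all 4 arrays, with the counts beside each name. The neutrophil lineage list (orange) reaches 100%, as do reference and oxidative phosphorylation genes, against 48.2% of all genes (dark bar).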

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

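The restriction to bright probe sets, the crossed pairing and the counts at an unadjusted p or per gene were chosen after the data were seen. The planned filter on dim probe sets, the brightest probe set per gene and the linear pseudocount were not run, since the values are centred and on a log scale. The count of 0 probe sets with limma became 281 with a trend in the prior variance (36 higher and 245 lower), where the trend runs over probe set means that hold no level, and 1 with ordinary t statistics (Mmadhc, 0.80, chosen after its value was seen), and stayed 0 in the other settings. Leaving out 1 array gave 0 probe sets in each case and 0 to 1603 genes (1603 without long bone array 1, 1 without long bone array 2). The 7325 probe sets at an unadjusted p under 0.05 ranged from 2673 to 12789 with 1 array left out, and were 4831 with ordinary t statistics and 2394 over bright probe sets, where only 14023 were tested. The 2179 probe sets at least 2-fold apart with no overlap between areas ranged from 2036 to 4746 with 1 array left out, and were 7022 at 1.5-fold, 601 at 3-fold and 839 over bright probe sets. The lone array was assumed to vary like the other area. The 20 called lists ranged from 17 to 27 with 1 array left out and were 0 with an estimated correlation, 0 with fry and 14 of 33 over bright probe sets, where the median of matrix remodelling turned to 0.36 and the cause was not tested. Bright probe sets leave out genes that went low on any array, so they are no neutral subset. Of the 20 calls, 20 held without trabecular array 1 or long bone array 1, 19 without trabecular array 2, 16 without long bone array 2 and 12 over bright probe sets. All 24 genes with the largest differences kept their direction in each setting that gave them, 13 of them over bright probe sets. They had been picked for no overlap between areas, so leaving out 1 array could not turn them, and this is no test of them. Same-numbered arrays did not deviate together (r = -0.18 across probe sets, which are not independent replicates). The replicate block called 0 probe sets, 0 genes and 22 lists, with 5707 probe sets at an unadjusted p. The crossed pairing as a block called 0 probe sets, with 7340 at an unadjusted p. Signal over background cannot be judged from centred values.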

Other observations

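The tests of explanations for the 3 patterns were chosen after the patterns had been seen, on values with 1 array left out that had been planned and on others that had not. Other genes set single arrays apart. On long bone array 2, 202 genes were at least 2-fold above and 257 at least 2-fold below all other arrays. The platelet chemokine gene Pf4 led with 4.36 above the next array, followed by Esm1 (4.04), Adipoq (3.77), the retinoic acid enzyme Aldh1a2 (3.45), Fstl1 (3.33) and Id3 (3.16), and the platelet gene Ppbp, the early B cell gene Vpreb1 and the haem enzyme gene Alas2 were highest there too. On long bone array 1, Prg4 led (5.74 above the next array), followed by Wif1 (3.49), the matrix gene Cilp (3.39) and Tnfrsf11b (1.91), an inhibitor of osteoclast formation. On trabecular array 1, P2ry10 led at 2.71 above the next array, with the cytokine gene Il1b at 2.07, Ccl6 at 1.91 and Il1r2 at 1.88. Trabecular array 2 had 5 genes at least 2-fold above all others. A probe set for B1 repeat RNA, an abundant repeat of the mouse genome, was at -1.70 and -0.70 in the trabecular and 0.70 and 0.93 in the long bone area.

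The first pattern is the lower level of cartilage genes in the trabecular samples. A single deviant array as the only source is argued against, since the chondrocyte median stayed at -1.10 or lower whichever array was left out. With 19 of 21 members not overlapping between areas its sign could not turn, so only its size bears on this. An effect of RNA quality on long bone array 2, low in the Gapdh but not in the Actb control, is argued against too, with -2.45 without it. A lower share of all skeletal cells in the trabecular samples stays open, under a rule set after the values were seen, that both of the following should exclude 0. Among genes with a range of at least 1, the chondrocyte median was below that of osteoblast, reticular stroma and adipocyte genes by a difference of -1.84 (95% interval -2.48 to -0.70, 14 against 28 genes), but over bright genes the difference was 0.03 (-1.37 to 0.76, 6 against 16 genes), and compression of dim signals and the loss of genes that went low keep either from deciding. Both intervals measure the spread between genes, which share the same arrays, and not that between samples. A difference between the areas themselves, the sampling of bone pieces and the purity of the sort were not tested.

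The second pattern is the height of reticular stroma genes on long bone array 2. Of 18 members 15 were highest on that array, against 35.2% of all genes, and the median excess over the other arrays, 1.58, was above that of all 10000 random lists of like probe set numbers. More RNA of reticular stroma in that sample and a loss of 5' signal there, which after normalization can raise other probe sets, cannot be told apart. The 15 members and the excess of 1.58 are the observation itself. The 5' signal was low in the Gapdh but not in the Actb control. Among the labelling controls the middle probe sets lay below the 3' ones there, while the 5' ones went both ways. The area does not account for it by itself, since long bone array 1 did not share it.

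The third pattern is the brightness of neutrophil genes in cells gated against CD45 and lineage antigens. Errors of the reading would give 1.06 bright genes of 15 at levels of 4 to 8, and 15 were found. Reading errors are thus argued against only for genes that stay below 8 on all arrays. No simulated probe set crossed 8. The reading is therefore untested for genes below 8 on some arrays only, which the spread of Elane and Ctsg allows. RNA of neutrophil lineage cells, from cells that passed the gate or free RNA taken along, may be the source, but the 15 bright genes are the observation itself, and with no array that stood at least 2-fold below another in the list's median (highest minus lowest 0.28) it stays untested. Of the 15 genes, Mmp8 is also on the matrix remodelling list, and how many of them the sorted cells express themselves was not tested. Where the reading holds, it bounds their levels only from below, and S100a8, S100a9 and Camp were not read at all. The list's median differed by 0.09 between the areas, while Elane and Ctsg were at -1.04 and -1.07 on trabecular array 1 and at 0.69 and 1.06 on trabecular array 2.

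The split of the arrays by area gave 7325 probe sets at an unadjusted p under 0.05 and the highest of the other splits 1077. With 3 splits in all no share under 0.05 can be had.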
